A study of Mus musculus with 12 samples.

How the data were processed

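Messenger RNA levels were measured by RNA sequencing in 12 libraries of HM1, a mouse ovarian cancer cell line, in 4 groups of 3: cultured cells carrying a control short hairpin RNA, cultured cells carrying a hairpin against St3gal3, and tumors of each of these lines. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 samples of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

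The authors deposited 1 table per sample with a gene identifier, name, description, length and TPM, a length-scaled share of the transcripts of a library, per the file headers and the values, which have the same sum in every sample to rounding and are given to 2 decimals. The submitters' processing notes name fastp, HISAT, RSEM and the build GRCm39, with no role, version or setting. RSEM estimates how reads are shared between similar transcripts, so levels of near-identical genes such as immunoglobulin segments, guanylate-binding proteins and histones are uncertain. Strand use in counting is not given in the sources used here. TPM keeps no depth, so the depth of each library is unknown and no counting interval is given. For cells 56061 genes are listed and for tumors 55878, of which 55425 identifiers are shared. Assembled-transcript identifiers mark 645 loci for cells and 462 for tumors, with 1.52 to 1.65% and 0.708 to 0.825% of all TPM. Their numbering is not comparable between the tables, and tests across tissues used the 55416 shared identifiers without them. Cell and tumor tables were normalized separately, so levels set across them are descriptive. Gene names came from the tables. No genome of the authors' build was used here, and no coordinates are given.

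The planned test was a quasi-likelihood test of counts. Because the tables hold TPM, the test named in the same plan for tables without counts was used: limma 3.58.1 in R 4.3.3 with a trended, robust empirical Bayes step on log2(TPM + 1), over genes with a mean of at least 1 TPM in some group. Fold changes are on that scale and understate changes of low genes. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Each tissue was fitted on its own 6 libraries, and the difference between the tumor and cell effects on all 12. Every adjusted p given for a gene comes from limma. No count was available for any other test.

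The 37 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and most of the other settings. Some genes belong to several lists, so list results are not independent. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 between genes, two-sided, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also takes its degrees of freedom from the few libraries, not from the genes. With 3 libraries per group, failing it does not show that correlation between genes undid a result. Fry asks whether a list's genes move one way and does not compare them with other genes. Overlap of calls was tested with Fisher's exact test, one-sided. List tests of the difference between tissues and 7 further marker lists were added after seeing the data.

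Genes were named by a rule: St3gal3; per comparison the 8 highest and 8 lowest changes among called genes with a mean of at least 2 TPM (in place of the planned CPM), no overlap between groups and no predicted or clone name; up to 4 members of each list that passed and up to 3 of any other list with at least 3 calls, by smallest p; in tumors Cd8a, Cd4, Gzmb, Ifng, Pdcd1, Cd274, Cxcl9, Cxcl10 and Ptprc; and 4 genes per direction for the difference, where the overlap criterion has no meaning. List members were dropped for length, keeping the smallest p. Genes of the closing observations were chosen after their values were seen.

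The procedure was tested on simulated data built from the real means and spreads, with 200 genes changed. At a log2 change of 1, 68% were recovered in cultured cells, 72% in tumors and 65% for the difference, over 13492, 14915 and 15381 genes. At a log2 change of 2 the shares were 91%, 86% and 85%. There were 8, 11 and 8 false calls. Each gene was drawn independently with normal noise, without correlation between genes or effects shared by the genes of a library. These figures may therefore look better than the real libraries allow. Alternatives were a pseudocount of 0.1, no filter, a stricter filter of 1 TPM in 3 libraries, a replicate block, leaving out each library, a minimum log2 change of 1, and all 4 groups in one fit. Median-of-ratios scaling, quantile normalization, array weights, only genes of at least 200 bases, and tumors without knockdown tumors 1 and 3 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.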

Results

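Transcript levels were compared between HM1 cells with a control hairpin and HM1 cells with a knockdown of St3gal3, in culture and in tumors, with 3 libraries in each of 4 groups. St3gal3 encodes a sialyltransferase, an enzyme that adds sialic acid to the ends of glycans. The series title places the comparison in the setting of tumor immunity. The depth of the libraries is unknown, because the tables hold TPM. Between 12629 and 13145 genes reached 1 TPM in a culture library, and between 14046 and 14534 in a tumor library. The 10 most abundant genes held 7.38 to 8.90% of all TPM. Across genes, log2 values of culture libraries correlated at 0.953 to 0.962 within a group and 0.952 to 0.967 between groups. In tumors these ranges were 0.959 to 0.968 and 0.943 to 0.961. Genes are not independent replicates, so these values only describe the libraries.

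St3gal3 (ENSMUSG00000028538) was lower in every knockdown library than in every control library of the same tissue. In culture it fell from 11.7 ± 1.82 TPM to 1.53 ± 0.290 TPM (SD, n = 3 each), which left 13.1% of the control mean, with a log2 change of -2.32 (SE 0.164, limma adjusted p = 0.00689). In tumors it fell from 14.9 ± 0.794 to 6.30 ± 0.848 TPM, a log2 change of -1.13 (SE 0.110, limma adjusted p = 0.00954). The loss was smaller in tumors, which also hold host cells, by 1.19 on the log2 scale in the test of the difference. Both calls held without any single library.

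**Figure D1:**
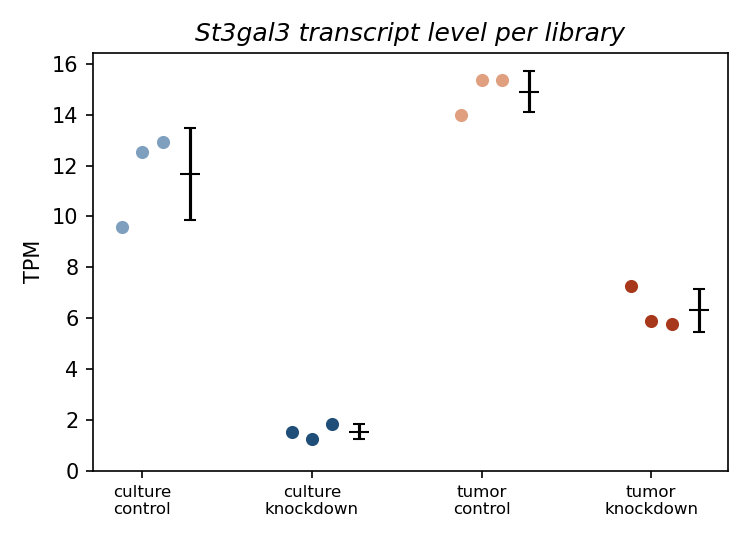
St3gal3 level in TPM (vertical axis) in each of the 12 libraries by group (horizontal axis), with the mean and SD of each group of 3 as a black mark and bar. Knockdown cultures lie between 1.25 and 1.83 TPM against 9.59 to 12.93 TPM in control cultures, and knockdown tumors between 5.76 and 7.28 TPM against 14.00 to 15.39 TPM in control tumors.

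In cultured cells the knockdown was compared with its control to see which genes differ in the absence of a host. Apart from St3gal3, few genes differed. Of 13492 genes tested, 4 were called by limma, 2 higher and 2 lower in knockdown cells, and 462 (3.42%) had an unadjusted p under 0.05. The other called genes have predicted or clone names and fall outside the rule for named genes. Gm15516 was listed at 0 in the 3 control libraries and at 12.88, 13.16 and 14.42 TPM in the knockdown libraries. Gm26602 was listed at 0 in control libraries and at 6.94, 5.23 and 9.97 TPM in knockdown libraries. ENSMUSG00002076529 was at 15.52, 10.81 and 12.82 TPM in control libraries and listed at 0 in knockdown libraries. Their listed lengths are 193, 285 and 109 bases.

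Of 19 lists tested in culture, 6 passed camera at the preset correlation, all downward, and 0 with an estimated correlation (lowest adjusted p = 0.599) or by fry (lowest adjusted p = 0.776). The 6 lists, of which only the first passed whichever library was left out, were immediate early genes (median log2 change -0.10), p53 targets (-0.06), the ER stress and integrated stress response (-0.06), EGFR and ERK targets (-0.10), hypoxia and glycolysis (-0.09) and cholesterol biosynthesis (-0.05). Not 1 member of these lists was called, and 0 were called when adjusted over the list alone. The members with the smallest p were Ier3 (log2 change -0.27, limma adjusted p = 0.993), Ccng1 (-0.26, 0.860), Xbp1 (-0.27, 1), Dusp5 (-0.21, 1), Pgam1 (-0.22, 1) and Cyp51 (-0.18, 1). Interferon-stimulated genes, with 9 members tested, had a median log2 change of 0.11 and MHC class I genes, with 18, one of 0.10, and neither list passed (camera adjusted p = 0.224 and 0.0922). The MHC class I list passed upward without control culture 3 (camera adjusted p = 0.0352) and without knockdown culture 1 (0.0227). Lists that passed downward in such an omission alone were chemokines (0.0293) and NF-kappaB targets (0.0173) without control culture 3, mitochondrially encoded genes without control culture 3 (0.0225) or knockdown culture 3 (0.00613), and sialyltransferases without knockdown culture 1 (0.0413). Mitochondrially encoded genes had a negative median (-0.08) and test direction but a positive mean (0.21), as did the epithelial and ovarian tumor list (median -0.08, mean 0.03), and sialic acid synthesis genes had a positive median (0.03) and a negative mean; no list of these passed (camera adjusted p = 0.0600, 0.131 and 0.556). Interferon-gamma-induced genes had a positive median (0.07) and mean (0.02) but a downward test direction against the other genes (camera adjusted p = 0.993). The sialyltransferase list, 10 genes with St3gal3 as its called member, did not pass with all libraries (camera adjusted p = 0.0853). It includes the target of the hairpin, which lowers its mean (-0.22) more than its median (-0.05). Its downward pass in an omission thus says little about the other members. The count of called genes was 15, 7 and 9 without control culture 1, 2 or 3, and 7, 7 and 11 without knockdown culture 1, 2 or 3. The hypoxia list turned upward, with no call, without control culture 3 (median 0.11).

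In tumors, where host immune and stromal cells are present, 18 of 25 interferon-stimulated genes and 4 of 15 genes of cytotoxic lymphocytes rose with the knockdown. Cxcl10, a chemokine that attracts activated T cells, rose from 22.6 ± 5.61 to 108 ± 22 TPM (SD, n = 3 each). Gzma, which encodes a protease of cytotoxic lymphocyte granules, rose from 2.03 ± 0.477 to 13.2 ± 3.13 TPM. Cd274, which encodes the checkpoint ligand PD-L1, rose from 19.8 ± 3.95 to 48.3 ± 5.34 TPM. Tff2, a trefoil factor of mucous epithelia, fell from 33.2 ± 14.2 to 3.89 ± 0.180 TPM. Of 14915 genes tested, limma called 225, of which 160 were higher and 65 lower in knockdown tumors, and 89 and 19 of these by at least 2-fold. An unadjusted p under 0.05 was found for 2787 genes (18.7%). All 225 called genes separated the groups without overlap, as did 24.7% of all genes tested, where chance gives 10%.

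The 8 largest increases among nameable genes were those of Gbp6 (log2 change 2.65, SE 0.385), Cxcl10 (2.22, SE 0.222), Gzma (2.21, SE 0.196), Gvin2 (2.06, SE 0.151), Gbp7 (2.04, SE 0.256), Gbp10 (2.03, SE 0.252), Cxcl11 (2.00, SE 0.262) and Ms4a4c (1.92, SE 0.206), with limma adjusted p from 0.00558 for Gvin2 to 0.0494 for Gbp6. Gbp6, Gbp7 and Gbp10 encode interferon-induced guanylate-binding proteins. Among the decreases, the smallest limma adjusted p was that of the microRNA gene Mir8094 (1.78e-06), which was at 37.56, 34.57 and 35.82 TPM in control tumors and listed at 0 in the 3 knockdown tumors, so no fold is given. In culture Mir8094, which is listed at 117 bases, went the other way, at 0 in control libraries and 49.34, 51.27 and 0 TPM in knockdown libraries, and was not called (limma adjusted p = 1). Among nameable genes, the largest decreases after it were those of Tff2 (-2.73, SE 0.272), Avil (-1.46, SE 0.168), H1f2 (-1.34, SE 0.210), Nr1d1 (-1.27, SE 0.206), Sparcl1 (-1.27, SE 0.143), Mest (-1.23, SE 0.140) and Dbp (-1.13, SE 0.200), with limma adjusted p from 0.0130 for Tff2 to 0.0494 for Dbp.

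Interferon-stimulated genes rose as a group. Of 25 members tested, 18 rose, 0 fell and all 25 had positive changes, with a median log2 change of 1.46 (camera adjusted p = 5.58e-35; adjusted p = 0.258 with an estimated correlation; fry adjusted p = 0.0120). Adjusted over the list alone, 24 rose. Ifit3 rose from 11.9 ± 1.16 to 40.4 ± 4.30 TPM, Ifit1 from 4.84 ± 0.130 to 16.2 ± 2.20 TPM, Oas3 from 7.08 ± 0.773 to 18.5 ± 0.512 TPM and Ifi44 from 4.90 ± 1.01 to 19.0 ± 1.70 TPM. Of 21 interferon-gamma-induced genes, 5 rose (19 when adjusted over the list alone), with a median of 2.22 (camera adjusted p = 1.74e-22; adjusted p = 0.258 with an estimated correlation; fry 0.0374). They included Cxcl10, Cd274, Gbp7 and Socs1, a feedback inhibitor of cytokine signaling (log2 change 0.75). Of the 21, 14 were called without control tumor 1, 2 without control tumor 2, 3 without control tumor 3, 1 without knockdown tumor 1, 0 without knockdown tumor 2 and 3 without knockdown tumor 3, with medians from 1.99 to 2.42. Of 19 genes of MHC class I antigen presentation, 4 rose (17 over the list alone): Psme2, from 330 ± 33.0 to 684 ± 101 TPM, H2-T23, Tapbp and Erap1. Their list had a median of 0.89 (camera adjusted p = 4.21e-18; adjusted p = 0.258 with an estimated correlation; fry 0.0439). The count of 4 was 10 without control tumor 1, 1 without control tumor 2 and 0 without knockdown tumor 1 or 2, with medians from 0.71 to 1.09 over all omissions.

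Of 15 genes of cytotoxic lymphocytes, 4 rose (13 over the list alone), with a median of 0.99 (camera adjusted p = 7.28e-13; adjusted p = 0.258 with an estimated correlation; fry 0.0172). Gzmb rose from 27.7 ± 1.41 to 74.0 ± 22.9 TPM, Prf1, the pore-forming perforin, from 12.2 ± 0.323 to 25.4 ± 5.09 TPM, and Klrd1 from 3.47 ± 0.513 to 7.87 ± 0.407 TPM. Without control tumor 2 the count was 2 and without knockdown tumor 1 it was 1. The T cell list rose with a median of 0.64 (camera adjusted p = 3.16e-09; adjusted p = 0.330 with an estimated correlation; fry 0.108), while 0 of its 19 tested members were called and 11 were when adjusted over the list alone. Cd3e was at 2.10 ± 0.805 and 5.11 ± 0.859 TPM (limma adjusted p = 0.0853) and Cd3d had an adjusted p of 0.139. Cd8a was at 1.76 ± 1.34 TPM in control and 5.04 ± 0.386 TPM in knockdown tumors (adjusted p = 0.193), with 0.24 TPM in control tumor 1. Cd4 was at 4.92 ± 1.62 and 5.29 ± 1.60 TPM (adjusted p = 0.870). Further genes named in advance did not pass limma's threshold: Ifng (0.570 ± 0.303 and 2.16 ± 0.560 TPM, adjusted p = 0.0799), Pdcd1 (1.99 ± 1.15 and 5.43 ± 1.25 TPM, 0.142), Cxcl9 (26.0 ± 15.3 and 80.7 ± 12.6 TPM, 0.189) and Ptprc, which encodes the leukocyte antigen CD45 (19.1 ± 1.69 and 27.9 ± 4.15 TPM, 0.0935). The checkpoint and regulatory T cell list rose with a median of 0.43 and Cd274 as its called member among 13, 3 when adjusted over the list alone (camera adjusted p = 1.20e-05; adjusted p = 0.258 with an estimated correlation; fry 0.0567). B and plasma cell genes rose as a list of 8 with a median of 0.90 and no called member (camera adjusted p = 0.00521; adjusted p = 0.463 with an estimated correlation; fry 0.345), and the list did not pass without control tumor 1. Its immunoglobulin gene Iglc1 ranged from 0.29 to 10.79 TPM in knockdown tumors.

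**Figure D2:**
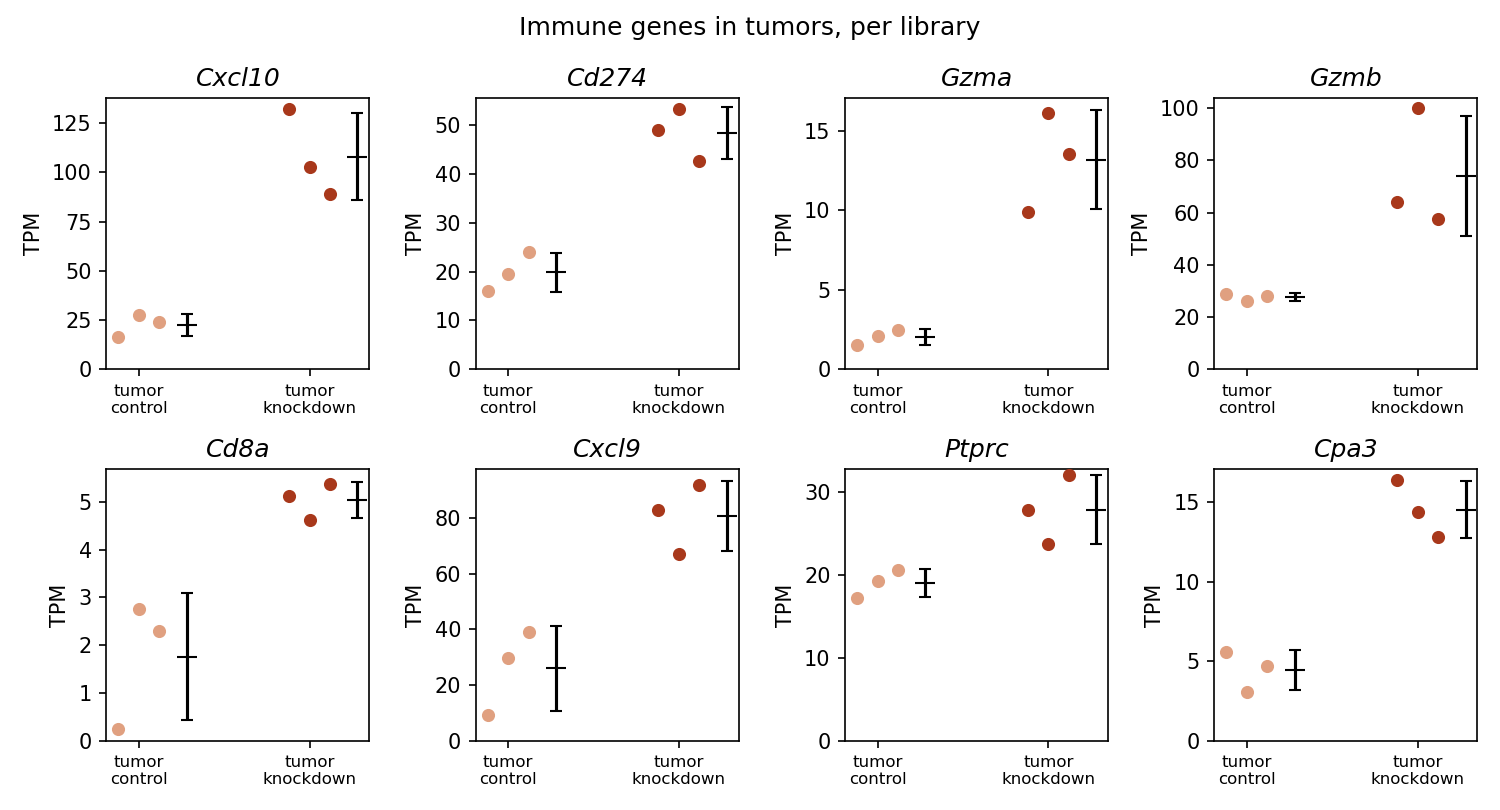
Level in TPM (vertical axes, each from 0) of 8 immune genes in the 3 control and 3 knockdown tumors (horizontal axis), with each group's mean and SD as a black mark and bar. Cxcl10, Cd274, Gzma, Gzmb and Cpa3 passed the test, and Cd8a, Cxcl9 and Ptprc did not (adjusted p = 0.193, 0.189 and 0.0935).

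Mast cell genes rose, with 5 of 9 called (7 over the list alone) and a median of 1.25 (camera adjusted p = 4.60e-09; adjusted p = 0.258 with an estimated correlation; fry 0.0317). Cpa3, the mast cell carboxypeptidase, rose from 4.43 ± 1.27 to 14.5 ± 1.80 TPM, and the tryptase genes Tpsab1 and Tpsb2 and the IgE receptor gene Fcer1a rose with log2 changes of 1.16, 1.26 and 1.25. The count of 5 was 3 without control tumor 1 or 3 and 0 without knockdown tumor 1 or 2, with medians from 1.07 to 1.35 over all omissions. Monocyte and macrophage genes had a median of 0.23 (camera adjusted p = 4.84e-06; adjusted p = 0.394 with an estimated correlation; fry 0.139), and 1 of 20 was called, 5 when adjusted over the list alone: Ly6c2, a marker of inflammatory monocytes, which rose from 9.49 ± 2.19 to 36.8 ± 7.92 TPM and was not called without control tumor 2 or knockdown tumor 1. Of 26 chemokine genes, Cxcl10, Cxcl11 and Ccl2 rose and Ccl22, which attracts regulatory T cells, fell from 23.9 ± 1.68 to 10.6 ± 2.44 TPM (5 up and 3 down when adjusted over the list alone; list median 0.17, camera adjusted p = 0.00437; adjusted p = 0.303 with an estimated correlation; fry 0.134). Classically activated myeloid genes rose with a median of 0.34 and Cxcl10 as the called member of 12, 2 when adjusted over the list alone (camera adjusted p = 0.000209; adjusted p = 0.258 with an estimated correlation; fry 0.0374). MHC class II genes rose with a median of 0.78 and 0 of 10 called (camera adjusted p = 0.000473; adjusted p = 0.463 with an estimated correlation; fry 0.345). H2-DMb2 and H2-DMb1 had log2 changes of 1.34 and 1.21 (limma adjusted p = 0.239 and 0.241). Cxcl10, the called member of the classically activated list, also belongs to the interferon-gamma-induced and chemokine lists. Cd274, the called member of the checkpoint list, belongs to the interferon-gamma-induced list too. The calls in these lists are therefore not separate results.

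Of 21 fibroblast and matrix genes, Fap, a protease of activated fibroblasts, fell from 7.35 ± 0.290 to 3.52 ± 0.339 TPM, and the list median was -0.32 (camera adjusted p = 0.0128; adjusted p = 0.630 with an estimated correlation; fry 0.279). All 15 endothelial genes had negative changes with a median of -0.32 and 0 were called (camera adjusted p = 0.00776; adjusted p = 0.628 with an estimated correlation; fry 0.296), Esam and Cdh5 among them with limma adjusted p of 0.127 and 0.205. The 4 erythroid genes tested, too few for a list test, had negative changes too, with a median of -0.72 and 0 called, and erythroid genes summed to 79.4, 108 and 99.4 TPM in control tumors and 88.3, 38.0 and 46.3 TPM in knockdown tumors 1, 2 and 3. The fibroblast list did not pass without control tumor 3 or knockdown tumor 1, nor the endothelial list without control tumor 1 or knockdown tumor 2. The epithelial and ovarian tumor list fell with a median of -0.26 and 0 of 8 called, 5 when adjusted over the list alone (camera adjusted p = 0.0293; adjusted p = 0.258 with an estimated correlation; fry 0.0189), with Msln at -0.64 and Krt19 at -0.32 (limma adjusted p = 0.0796 and 0.0894). This list did not pass without knockdown tumors 1 and 3 (camera adjusted p = 0.315), which held more skeletal muscle transcripts than the other tumors. Of 14 p53 targets Phlda3 fell (log2 change -0.40), a call lost in each of the 6 omissions of a library, and 6 did when adjusted over the list alone, with a list median of -0.24 (camera adjusted p = 0.00304; adjusted p = 0.258 with an estimated correlation; fry 0.0255). Immediate early genes had a median of -0.22 and 0 of 13 called, 2 when adjusted over the list alone (camera adjusted p = 0.00243; adjusted p = 0.436 with an estimated correlation; fry 0.0989), with Jun at -0.33 and Nr4a1 at -0.56 (limma adjusted p = 0.0539 and 0.0724).

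Smaller shifts were those of mitochondrially encoded genes (median 0.20, camera adjusted p = 0.00243; adjusted p = 0.339 with an estimated correlation; fry 0.158), proliferation genes (0.05, 0.0133; adjusted p = 0.630 with an estimated correlation; fry 0.686) and cholesterol biosynthesis (0.10, 0.0366; adjusted p = 0.679 with an estimated correlation; fry 0.686), each with 0 called members. The smallest p in these lists were those of mt-Nd1 and mt-Atp8 (limma adjusted p = 0.151 and 0.214), Pcna and Cdk1 (0.115 and 0.237), and Nsdhl and Idi1 (0.271 and 0.307). Proliferation and cholesterol lists did not pass without control tumor 1, control tumor 3 or knockdown tumor 1, and the cholesterol median was -0.05 without knockdown tumor 1. Skeletal muscle transcripts were higher in knockdown tumors, with a median of 1.49 over 12 genes, 0 of them called (camera adjusted p = 2.88e-07; adjusted p = 0.339 with an estimated correlation; fry 0.134). Acta1, skeletal muscle actin, was at 33.03, 3.50 and 23.73 TPM in knockdown tumors 1, 2 and 3 and at 0.42, 3.73 and 0.11 TPM in control tumors 1, 2 and 3. Tnni2 and Mylpf had limma adjusted p of 0.156 and 0.179. Without knockdown tumors 1 and 3, an alternative added after seeing the data, 72 genes were called, 19 of them among the 225, and 5 of the 25 interferon-stimulated genes, with a median of 1.42. In that fit 0 genes of the interferon-gamma, MHC class I and mast cell lists were called by limma, with medians of 2.41, 0.94 and 1.29, and 14 of the 21 lists passed camera. Those that did not were B and plasma cells (adjusted p = 0.673), MHC class II (0.055), chemokines (0.055), proliferation (0.055), mitochondrially encoded genes (0.0545), cholesterol biosynthesis (0.352) and the epithelial and ovarian tumor list.

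The sialyltransferase list, 12 genes with St3gal3 as its called member (3 when adjusted over the list alone), and the list of Siglec receptors, which bind sialic acid, did not pass in tumors (camera adjusted p = 0.184 and 0.669). Dendritic cell, neutrophil, hypoxia and NF-kappaB lists did not pass either (0.270, 0.617, 0.343 and 0.161). The ER stress list, which did not pass (0.0894), had a negative median (-0.12) and test direction and a positive mean near 0, and the NF-kappaB list a negative median near 0 and a positive mean (0.11) and test direction. In omissions of a library, camera passed for neutrophils upward without control tumor 1 (adjusted p = 0.0143), and downward for ER stress without control tumor 2 (0.0396), sialic acid synthesis and removal without knockdown tumor 1 (0.0224) and TGF-beta and SMAD targets without knockdown tumor 3 (0.0396). Of the 33 lists tested in tumors, 21 passed camera, 0 with an estimated correlation and 9 by fry, of which 8 passed both camera and fry. The ninth by fry was sialic acid synthesis and removal (median -0.20, fry adjusted p = 0.0374, camera 0.0648). The epithelial and ovarian tumor list failed with an estimated correlation although that correlation, -0.091, was below the preset 0.01. Failure there is thus not a matter of correlation between genes alone. Other lists that passed had estimates far above the preset. These were 0.5 for interferon-stimulated, 0.88 for interferon-gamma-induced, 0.78 for MHC class I and 0.94 for MHC class II genes, for example. Those of chemokines (0.058) and p53 targets (0.044) lay nearer to it. Where the estimate is high, the camera p at the preset correlation overstates the evidence. The number of called genes was 103 without control tumor 2, 131 without control tumor 3, 38 without knockdown tumor 1 and 65 without knockdown tumor 2. Of the 39 named called genes, 8 kept their call whichever library was left out: St3gal3, Ifit1, Ifit3, Ifi44, Oas3, Gvin2, Gzma and Mir8094. Gbp6, Socs1, Erap1 and Ccl2 kept it in 1 of 6 omissions and Phlda3 in 0. In all, 31 lost it in some omission, 28 of them without knockdown tumor 1, 23 without knockdown tumor 2, 15 without control tumor 2, 13 without control tumor 3, 9 without control tumor 1 and 7 without knockdown tumor 3.

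The last comparison asked whether the effect of the knockdown differed between tumors and culture. Limma called a more positive change in tumors for 14 of 25 interferon-stimulated genes and for 4 of 15 genes of cytotoxic lymphocytes. Most members of both lists were near 0 in culture, where 9 and 2 were high enough to test. Iigp1, an interferon-induced GTPase, was at 20.8 ± 11.8 and 180 ± 56.4 TPM in control and knockdown tumors and at 0.0533 ± 0.0321 and 0.0167 ± 0.0153 TPM in culture, a difference of 3.26 on the log2 scale (SE 0.601, limma adjusted p = 0.0434). The serpin gene Serpina3f (difference 2.81, SE 0.511, adjusted p = 0.0330) and the immunoglobulin segment Ighv3-1 (2.86, SE 0.564, adjusted p = 0.0484) were also near 0 in culture. In tumors alone these 3 genes did not pass (limma adjusted p = 0.0845, 0.0807 and 0.0818). Tff2 (-2.74, SE 0.321, adjusted p = 0.00445) and Mest (-1.46, SE 0.192, adjusted p = 0.00692) were near 0 in culture as well. Avil and Nr1d1 were present in both. Avil was at 12.7 ± 1.72 and 12.6 ± 0.719 TPM in control and knockdown cultures and at 14.5 ± 2.56 and 4.66 ± 1.02 TPM in tumors (difference -1.46, SE 0.216, adjusted p = 0.0124). Nr1d1, a clock repressor, had a difference of -1.41 (SE 0.271, adjusted p = 0.0402). The small nucleolar RNA gene Snord12, listed at 90 bases, was listed at 0 in all 6 tumors and all 3 knockdown cultures and at 121.95, 138.28 and 19.02 TPM in control cultures, so its difference comes from culture. Of these 8 genes Avil, Mest, Tff2 and Snord12 kept their call in all 12 omissions of a library, Iigp1 and Serpina3f in 4, Nr1d1 in 3 and Ighv3-1 in 2.

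Of 15381 genes tested for this difference, limma called 116, 88 with a more positive and 28 with a more negative change in tumors, and 1702 (11.1%) had an unadjusted p under 0.05. With a pseudocount of 0.1 the count was 26. It was 72, 68 and 67 without control culture 1, 2 or 3, 74 and 69 without knockdown culture 1 or 3, and 71 without knockdown tumor 1. Relabelling the libraries within tissue gave as many calls in 7 of 100 groupings, the real one included: in 6 of the 7 that keep the real tumor grouping and in 1 of the other 93. Of 12091 genes tested in both tissues, 1 was called lower in both, and this was St3gal3, the target of the hairpin, so that the overlap (Fisher's exact test, one-sided, p = 0.00727) rests on the target alone and is 0 without it. In both tissues 0 genes were called higher (Fisher's exact test, one-sided, p = 1), with 1 higher and 2 lower genes called in culture among them. Of 122 genes called in tumors and tested in culture, 81 (66.4%) had the same sign in culture, against 50.8% of all genes tested in both. The 50.8% is not matched for direction. The median culture change was 0.0831 for the 78 genes higher in tumors, -0.00854 for those lower, and 0.0216 over all genes tested in culture. Across genes, the 2 sets of changes had a Pearson r of -0.0615 and a Spearman rho of 0.0506, where genes are not independent replicates.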

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

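The tests of the interferon pattern and the list tests of the difference were chosen after the result was seen. The tests of clock genes and of genes listed at 0 were chosen after the pattern was noticed but before their own values were seen. For genes listed at 0, the reading of the comparison with tumors was changed after its value was seen. The genes and lists of the next 2 paragraphs were singled out because the test of the difference between the tumor and the cell effect passed. Their values are tumor minus cell log2 changes. Most of these genes lie near 0 in culture, where a change is hard to measure.

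Among interferon-induced genes the differences were 3.26 for Iigp1, 2.60 for Gbp6, 2.06 for Gbp7, 2.05 for Gbp10, 1.91 for Gvin2, 1.76 for Ifi44, 1.74 for Ifit3, 1.52 for Ifit1, 1.00 for Socs1 and 2.81 for Serpina3f. Among chemokines and the checkpoint ligand they were 2.35 for Cxcl10, 1.98 for Cxcl11, -1.11 for Ccl22 and 1.33 for Cd274. The antigen presentation genes Tapbp and H2-T23 had 1.00 and 0.87. The cytotoxic genes Gzma, Gzmb, Prf1 and Klrd1 had 2.26, 1.37, 1.00 and 0.99. The mast cell genes Cpa3, Tpsb2, Fcer1a and Tpsab1 had 1.52, 1.26, 1.25 and 1.04. Ly6c2 and Ms4a4c had 2.08 and 1.92, and Ighv3-1 had 2.86. St3gal3 itself had 1.19. Lower in tumors than in culture by this measure were Tff2 (-2.74), Mest (-1.46), Avil (-1.46), Nr1d1 (-1.41), Sparcl1 (-1.37) and Fap (-0.89). Snord12, with a fitted 6.13, was listed at 0 in all tumors.

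For gene lists the median differences were 2.35 for interferon-gamma-induced genes, 1.39 for interferon-stimulated genes, 0.86 for MHC class I and 0.80 for MHC class II genes, 0.99 for cytotoxic lymphocytes, 0.63 for T cells, 0.32 for checkpoints and regulatory T cells, 0.90 for B and plasma cells, 1.25 for mast cells, 0.23 for monocytes and macrophages, 0.36 for classically activated myeloid cells and 0.12 for chemokines. They were 1.44 for skeletal muscle, 0.26 for mitochondrially encoded genes, 0.13 for cholesterol biosynthesis, -0.33 for fibroblasts and -0.37 for endothelial cells. With an estimated correlation 2 of these lists passed camera, interferon-stimulated genes and cytotoxic lymphocytes (adjusted p = 0.0214 each). In tumors alone both had a camera adjusted p of 0.258 with an estimated correlation. The fit of the difference takes its spread from all 12 libraries. Most members of both lists are near 0 in culture and add little spread there, so this pass is not firmer evidence.

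Relabelling libraries within tissue gave at least the real 116 calls in 7 of 100 groupings, and 467 at most among the others, a share that is not under 0.05, so chance is not excluded by this count. The 100 include 7 that keep the real tumor grouping, and with it the tumor signal, of which 6 reached the count, the one with 467 calls among them. Of the other 93, 1 reached it, with 323 calls, and what sets it apart was not tested. In tumors the real grouping gave 225 calls and the highest other of the 10 splits 6, and 1 split reached the real count. In culture the real grouping gave 4 and the highest other 7, and 3 splits reached the real count. With 10 splits no share under 0.05 can be had.

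The rise of interferon-stimulated genes was set against 3 explanations. A direct effect of the knockdown in HM1 cells, the same in culture, would need a culture median of at least 0.5 times the tumor median. Over the 9 members tested in both, the tumor median was 1.27 and the culture median 0.108 (SD 0.145), below that bound. However, only 7 list members reached 1 TPM in every culture library. Isg15 was at 1.22 ± 0.126 TPM in control and 1.45 ± 0.575 TPM in knockdown cultures. At such levels log2(TPM + 1) understates a change, so the bound does not exclude a direct effect. An even rise of all leukocytes alone would raise pan-leukocyte genes as much. These had a median of 0.325 and a highest change of 0.634 over 8 genes, while 23 of the 25 list members lay above that highest change. After median-of-ratios scaling the list median was 1.5. Scaling shifts all genes of a library alike, and the median change over all tumor genes was -0.0532 before it and -0.00348 after. Scaling can thus account for little of the rise, but this was settled by all genes and is no separate test of the list. The pan-leukocyte values argue against an even rise of all leukocytes as the whole cause. They do not address a change in the mix of leukocyte types, which was not tested. List medians differed between types, with 0.99 for cytotoxic lymphocytes, 1.25 for mast cells and 0.23 for monocytes and macrophages. A stronger interferon signal within tumors may be a candidate explanation. It was not tested, and these libraries do not separate it by cell type.

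Clock output genes, noticed through Nr1d1 and Dbp, had a median of -0.465 over 9 genes in tumors, 7 of them negative. The 9 include Nr1d1 (-1.27) and Dbp (-1.13), the only 2 called, so the list partly restates its selection. Per1 (0.36) and Ciart (0.09) had positive changes. A shared effect of the knockdown in HM1 cells is argued against by the culture median of the 9 genes, -0.00223 (SD 0.113). The tumor median it is set against includes Nr1d1 and Dbp. Collection of the 2 groups of tumors at different hours would be expected to raise genes of opposite phase, whose median over 3 genes was 0.058, between the bounds set for and against. It cannot be told apart from an effect of the knockdown on the host or tumor, because collection times are not given in the sources used here.

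In culture 19 tested genes were listed at 0 in every library of 1 group and above 0 in every library of the other, 11 of them at 0 in control. Among them 63.2% were under 200 bases, against 3.84% of all genes tested (Fisher's exact test, one-sided, p = 3.57e-13), which is consistent with unstable TPM of short transcripts. Of the 18 that the tumor tables list, 0 had the same pattern in tumors. By the bound set beforehand this would count against a knockdown effect that tumors share. That bound was set aside after the value was seen, since tumors hold host cells. St3gal3 itself was left at 42.3% of control in tumors against 13.1% in culture, so such an effect is not excluded. The real grouping gave 19 such genes and the highest other split 14, 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05.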

How the results depend on the processing

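Median-of-ratios scaling, quantile normalization, array weights, the 200-base minimum and the fit without knockdown tumors 1 and 3 were chosen after seeing the data. Depth is unknown in TPM tables, so no limit from depth can be given. The planned count-based alternatives (other size factors, a Wald test, voom with and without quality weights, and the overlap of their calls) were not run, because they need counts. Where 1 library of a group was left, it was assumed to vary like the other group. Except where the construction shows it (fewer libraries, or more libraries sharing one estimate of spread), the cause was not tested.

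Called genes in culture, 4, became 11 with a pseudocount of 0.1, and 8 with the stricter filter, with all 4 groups in one fit and with array weights; leaving out single libraries gave 7 to 15. Called genes in tumors, 225, became 82 without a filter, 599 with all groups in one fit, 795 with array weights (370 higher, 425 lower), 108 with a minimum log2 change of 1, 72 without knockdown tumors 1 and 3, and 38 to 229 without single libraries. The 116 calls for the difference became 26 with a pseudocount of 0.1, 195 with quantile normalization, 259 with array weights and 67 to 164 without single libraries. St3gal3 in tumors was at -1.21 without knockdown tumors 1 and 3 (adjusted p = 0.0531; 0.0009 to 0.0768 over its alternatives). With an estimated correlation 0 lists passed in culture and 0 in tumors, and by fry 0 and 9. Without single libraries 4 to 8 lists passed in culture and 18 to 22 in tumors.

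Replicate numbers did not pair the libraries: correlations of deviations were -0.060, -0.065 and -0.16 in culture and -0.14, -0.017 and 0.049 in tumors. With the replicate block, 4 genes were called in culture, 2 in tumors and 0 for the difference, St3gal3 in tumors was at -1.13 (adjusted p = 0.0768), and 5 and 21 lists passed.

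Of 1278 other values of 78 gene results, 1007 kept direction and side of the threshold, 243 lost and 25 gained a call, and 3 turned, all of Cd4 in tumors, which was not called: -0.0612 without control tumor 2, -0.0593 without knockdown tumor 1 (range without single libraries -0.0612 to 0.314) and -0.36 without knockdown tumors 1 and 3. Of 605 list values 493 were the same, 75 lost and 12 gained a call, and in 25 the direction of the test turned, with 0 of the 25 past the threshold. Of these, 3 belong to lists that passed: the hypoxia and glycolysis list in cultured cells (median 0.108 without control culture 3, range without single libraries -0.26 to 0.108) and the cholesterol biosynthesis list in tumors (-0.0456 without knockdown tumor 1, range -0.0456 to 0.172, and -0.125 without knockdown tumors 1 and 3).

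The other 22 belong to lists that did not pass, whose medians need not turn with the test. Without single libraries, medians in culture ranged from -0.033 to 0.0407 for the sialic acid synthesis and removal list in cultured cells, from -0.0462 to 0.147 for the interferon-gamma-induced genes list in cultured cells (0.0724 by fry, 0.055 with median-of-ratios scaling), from -0.0906 to 0.038 for the chemokines list in cultured cells and from -0.0205 to 0.0801 for the proliferation list in cultured cells. In tumors they ranged from -0.177 to 0.203 for the Siglec receptors list in tumors, from -0.14 to 0.292 for the neutrophils list in tumors (0.0575 by fry) and from -0.102 to 0.0166 for the epithelial-mesenchymal transition list in tumors. Without knockdown tumors 1 and 3 the medians were -0.275 for the Siglec receptors list in tumors, -0.016 for the neutrophils list in tumors and -0.237 for the dendritic cells list in tumors.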

Other observations

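Genes and lists of this part were chosen after seeing the data, some with called genes already in them, and the lists of the first 2 paragraphs had no list test. Of 8 genes of pericytes, mural cells of small vessels, all had negative changes in tumors, with a median of -0.62, and 3 fell by limma's test, Rgs5 (log2 change -0.84, adjusted p = 0.0266), Kcnj8 (-0.85, 0.0464) and Abcc9 (-0.95, 0.0396). All 12 genes of a basement membrane list had negative changes, with a median of -0.54. Of these 6 fell: Hspg2 (-0.75), Col4a5 (-0.68), Col4a1 (-0.59), Col4a2 (-0.57), Col18a1 (-0.44) and Sparcl1. In culture the 9 basement membrane genes tested had a median of -0.08 and 0 were called. Sparcl1, which is not a structural basement membrane component, had been seen as a called gene before it was placed in that list.

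Of 13 histone genes tested in tumors, 4 fell by limma's test, and all 13 changes were negative, with a median of -0.58. The 4 were H1f2 (-1.34), H2bc18 (-1.28), H2bc4 (-1.09) and H4c9 (-0.56). In culture the 9 tested had a median of -0.08 and 0 were called. Proliferation genes did not fall with them in tumors (median 0.05). Histone copies are near-identical, and messages of this class mostly lack a poly(A) tail, so their levels also depend on how libraries were made. Natural killer cell genes, 6 tested, all had positive changes with a median of 0.90, and Gzma was the called one. The cytotoxic list also holds Gzma, Klrb1c, Klre1 and Ncr1 of these, so the median largely restates that list.

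Of 12 genes of exocrine pancreas enzymes and their cofactors, 9 reached 1 TPM in every culture library, while Amy2a5 was listed at 0 in at least 1 of them. Ctrb1 had a mean of 21.9 TPM in culture (19.45 to 24.99) and 0.0117 TPM in tumors. Try4 had 6.79 TPM in culture, Cela2a 7.15, Cela3b 2.89, Pnlip 2.16 and Clps 1.88 TPM, and all 5 were listed at 0 in all 6 tumors. Prss2 had 9.50 TPM in culture and 1.03 TPM in tumors, Cpa1 1.66 and 0.655 TPM. Cela1 had 48.1 and 56.4 TPM, and differed in that from the rest. The insulin genes Ins1 and Ins2 had 0.0117 and 0.0250 TPM in culture. The keratins Krt8, Krt18 and Krt19 had 58.6, 61.8 and 68.3% of their culture level in tumors. In culture the list did not pass between knockdown and control (camera adjusted p = 0.156). Cell and tumor tables were normalized separately, and the comparison with keratins and the choice of these genes were made after their levels were seen, so no explanation is drawn.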
